A study of Listeria monocytogenes with 8 samples.

How the data were processed

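RNA of Listeria monocytogenes H7858 from 4 CSS and 4 MBHIB samples was depleted of rRNA, made into libraries with a ScriptSeq kit and sequenced as 100 bp single reads. Per the submitters' processing notes, BWA and SAMtools were used; their versions are not given. The deposited original table holds a coverage value per gene and library, per the file headers, as whole numbers on no common scale; from their size they are read depth summed over the bases of a gene. Per the file headers, the deposited second table holds normalized coverage of the 2904 protein-coding loci, in which the library sums are nearly equal. Per the file headers, it also gives the authors' baySeq likelihood of a difference, which was not used, their false discovery rate, a quantity of the q-value type deposited by the authors, and the fold, the deposited ratio of CSS over MBHIB, with no number for 7 loci. The genome build, read filters and strand handling are not given in the sources used here. Overlapping genes, antisense genes and near-identical copies are therefore uncertain.

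The original table has 2974 entries: 2904 protein-coding, 14 rRNA and 56 tRNA. The files pair 2614 of them with an EGD-e gene and 2795 with an H7858 locus tag; 2613 of the EGD-e tags are in the EGD-e reference gene table (assembly ASM19603v1), used for names only. A symbol was found for 726. Coordinates are those of the authors' H7858 annotation. Genes with a symbol carried by more than 1 entry are named with their locus in the tables.

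The design foresaw read counts or a signal; the values were a signal, so the test written for that case was used. Each library was divided by a scale factor, the median over genes of the ratio to the geometric mean over libraries. A pseudocount of 292 scaled units, the 5th percentile of the values above 0, was added before taking log2, which shrinks the fold changes of genes with low coverage. Genes above the pseudocount in at least 4 libraries were kept (2737; 167 were left out), and rRNA and tRNA were left out of the scale factors and the test. limma 3.58.1 with statmod 1.5.0 in R 4.3.3 (lmFit, eBayes with trend and robust) compared CSS with MBHIB without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05; for the 2-fold count the absolute log2 fold change had to be at least 1. The number of changed genes with a standard error above 0.5 on the log2 scale was 56. Tables were read with Python 3.11.15 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

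The groups, tests, alternatives, rule for named genes and 41 gene lists were fixed before the data were examined. Lists with at least 3 measured members (40) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. fry asks whether a list moves on balance one way and does not compare it with other genes. The ribosomal list matched 2 genes, since the product texts name subunits otherwise than its pattern, and a rewritten list was added. The named genes are the 6 largest rises and 6 largest falls among changed genes with non-overlapping groups and a known product, the 2 smallest p-values in each of the 10 lists with the smallest camera p, and always prfA, hly, actA, inlA, sigB, agrA, flaA, eutB, pduC and cspB; a gene named by more than 1 part counts under each. Other genes given as examples of a list, namely those beyond this rule, were chosen after their values were seen. Of the 41 named genes, 34 passed.

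Shares of rRNA, of tRNA and of the 10 most covered genes were compared by exact two-sided permutation tests over 70 splits. The authors' calls were taken from their table with a fold of at least 2.5 or at most 0.4 and a false discovery rate under 0.05. The values are sums over bases and not counts of reads, so no counting intervals were given; the depth behind a value is the mean read depth printed with it.

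Alternatives were quantile normalization, array quality weights, no filter or a 10 times stricter filter on low values, a replicate block, each library left out in turn, rRNA and tRNA kept, the authors' normalized table, a pseudocount 10 times as large or of 1, and, added after the data were seen, CSS 2 and MBHIB 3 left out together and list members by symbol or locus tag alone. All 35 splits of the 8 libraries into 4 and 4 were refitted. The fit was tested on 5 simulated tables of 2615 genes on average with 200 changed. It recovered 70.9% of 2-fold and 94.1% of 4-fold changes, with 3.83% false calls and 0 wrong signs. In 1 further simulated table where nothing was changed it made 0 calls. The list test found 5 of 5 shifted lists and called 0 of 100 unshifted ones in simulations of 2737 genes. All these simulations drew the noise of each gene on its own, and their lists held random genes. They therefore do not show how the list test behaves for correlated genes. In the real lists the estimated correlation reached 0.873 (ethanolamine). A GC check was not possible without the genome sequence.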

Results

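The transcriptome of Listeria monocytogenes strain H7858, a foodborne pathogen that grows at refrigeration temperature, was sequenced after growth on a ready-to-eat fish and in a laboratory broth. Cells had spent 7 days at 7 °C either on cold smoked salmon (CSS, 4 libraries) or in modified BHI broth (MBHIB, 4 libraries) and were collected in late log phase. The labels give mean log CFU densities of 8.17 ± 0.16 (CSS) and, for the broth, 8.28 ± 0.21; the kind of error is not stated, and the printed units (per ml for the fish, per g for the broth) look exchanged. Ribosomal RNA was depleted, and single reads of 100 bp were made. Each gene has a summed coverage, the read depth added up over its bases. The totals, in 1e+06 bases, were 131, 171, 491 and 493 in MBHIB 1 to 4 and 134, 198, 290 and 272 in CSS 1 to 4. Those sums equal 1.31 to 4.93 times 1e+06 full-length reads per library, and the numbers of reads themselves were not given. Values below are mean read depths per base after scaling between libraries, with the SD and n = 4 per group. Log2 fold changes are CSS minus MBHIB, taken between means of log2 values with the pseudocount added. They therefore need not match the ratio of the mean depths printed beside them, above all where libraries of a group differ widely.

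The comparison of CSS with MBHIB asks which genes this bacterium uses differently on the fish than in broth at the same temperature. On salmon, genes that make cobalamin (vitamin B12) gave 5 of the 6 largest rises among changed genes with non-overlapping groups and a known product. These 5 genes lie in 1 block of 20 neighbouring genes that all rose, so they are not separate results. The ranking depends on the pseudocount, which shrinks rises from low coverage. It also differs by the authors' fold. By that measure arcB (31.4), lmo0037 (19.6), lmo2799 (19.3), lmo0039 (18.3), lmo0481 (17.5), aguA1 (13.7) and nanE (13.0) rose more than lmo1201 (12.6). So did cobD of the cobalamin block (12.9). Of the cobalamin list 23 of 29 measured members rose, of the propanediol list 12 of 19 and of the ethanolamine list 9 of 19. When any of 6 libraries was left out, the propanediol list had 7 higher and the ethanolamine list 0 or 1. The propanediol list holds 30 genes, of which 19 were measured. Its rising members included genes annotated to ethanolamine use or B12 synthesis. The uroporphyrinogen-III methyltransferase gene lmo1201 went from a depth of 5.72 ± 8.77 in MBHIB to 80.0 ± 17.2 in CSS (SD, n = 4), a log2 fold change of 4.94. Of the pyrimidine synthesis list 10 of 12 members fell. Genes pyrE to pyrP lie in 1 run of 9 neighbouring genes that all fell, so they are not separate results. Of the citrate cycle and pyruvate dehydrogenase list 7 of 7 fell (2 without MBHIB 2, CSS 3 or CSS 4). None of these lists passed camera, a test of whole lists, with an estimated correlation (adjusted p = 0.490 for cobalamin, propanediol and pyrimidines and adjusted p = 0.527 for the others, with an estimated correlation). The trehalose-6-phosphate hydrolase gene lmo1254 fell from 24.0 ± 2.92 to 4.5 ± 5.95 (log2 fold change −3.09). Of 10 measured members of the list for the regulon of the virulence regulator PrfA, 6 rose, from mean depths of 0.349 to 6.39 in broth, among them the listeriolysin gene hly and the actin-assembly gene actA (adjusted p = 0.490 for the list with an estimated correlation).

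Of 2737 protein-coding genes tested, 598 changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 281 higher and 317 lower on salmon. A total of 258 changed at least 2-fold, 145 higher and 113 lower. The groups did not overlap for 746 genes (27.3%), where chance gives 2.86%. The first principal component held 62.1% of the variance and separated the groups, the second 13.0%. CSS 2 (7.72) and MBHIB 3 (−9.68) lay nearest to the other group on the first component, and CSS 2 correlated better with MBHIB 3 (0.981) than with any CSS library (at most 0.976). The number of changed genes was 373 without MBHIB 1, 287 without MBHIB 2, 337 without CSS 1, 363 without CSS 3 and 360 without CSS 4. The labels say that there were 4 libraries per group but not whether they came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical.

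**Figure D1:**
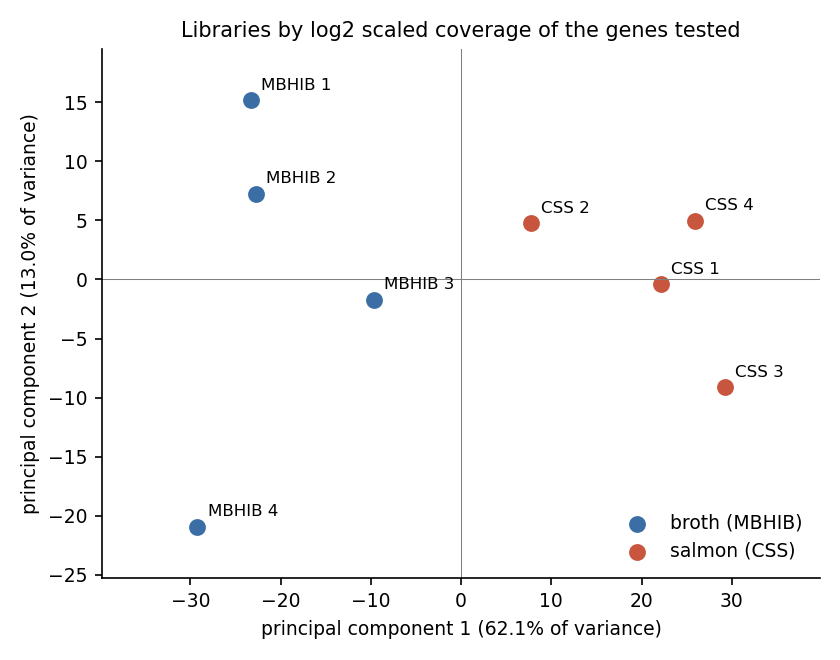
Principal components 1 (62.1% of the variance) and 2 (13.0%) of the log2 scaled coverage of the 2737 genes, 1 point per library, coloured by group. The 4 MBHIB libraries lie at negative and the 4 CSS libraries at positive values of component 1, with MBHIB 3 (−9.68) and CSS 2 (7.72) nearest to each other.

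Of 29 measured members of the cobalamin synthesis list, 23 were higher on salmon and 0 lower (24 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 3.70 (2.16 with a pseudocount 10 times as large). The list passed camera with its preset correlation (adjusted p = 1.67e-12), but not with an estimated correlation (adjusted p = 0.490 with an estimated correlation). Largest among changed genes with non-overlapping groups and a known product were the rises of lmo1201 (coordinates 1019850 to 1021331 on the authors' map of H7858, standard error 0.93, adjusted p = 0.0108), cbiD (1014333 to 1015454, 2.66 ± 4.22 to 33.7 ± 3.59, log2 fold change 4.61), cbiL (1022106 to 1022816, 4.57), cbiH (1018376 to 1019101, 4.55) and cbiG (1017348 to 1018379, 4.45), all steps of the corrin ring pathway. The smallest p-values in the list belonged to cobQ, a cobyric acid synthase (24.5 ± 7.70 to 79.9 ± 13.1, log2 fold change 1.73, standard error 0.21, adjusted p = 0.00336), and to lmo1207, the ATPase of a cobalt transporter (7.87 ± 5.0 to 46.1 ± 8.49, 2.65). In MBHIB 3 the median of the list stood at 2.10 above the broth mean on the log2 scale, and in the other broth libraries between −1.04 and −0.12. Leaving out MBHIB 3 raised the log2 fold change of gene lmo1201 to 5.89, and leaving out MBHIB 4 lowered it to 4.18. The genes cbiD, cbiL and cbiH shifted alike (5.50, 5.40 and 5.46 without MBHIB 3; 3.95, 3.86 and 3.87 without MBHIB 4), and cbiG was 5.29 without MBHIB 3. With a pseudocount 10 times as large, gene cbiD was 3.05 and gene cbiG 2.80.

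Genes for ethanolamine use, a pathway that takes carbon and nitrogen from a membrane lipid head group, had 9 of 19 measured members higher on salmon and 0 lower (17 higher adjusted over the list alone). The ethanolamine permease gene lmo1186 (1008079 to 1009200) went from 15.4 ± 10.5 to 99.9 ± 18.5 (log2 fold change 3.25, standard error 0.84, adjusted p = 0.0302), and lmo1190, annotated as part of a B12-regulated transporter, from 16.3 ± 18 to 151 ± 48.9 (3.95, adjusted p = 0.0216). The ammonia-lyase gene eutB did not pass the test (14.2 ± 9.38 against 77.1 ± 16.0, adjusted p = 0.0627), although its groups did not overlap. The list passed camera at the preset correlation (adjusted p = 7.10e-06; adjusted p = 0.527 with an estimated correlation). MBHIB 4 stood apart here, with a list median of −2.93 against the broth mean where the other broth libraries had 0.51 to 1.32. The list had 17 genes higher without MBHIB 4, 1 without MBHIB 1, 1 without CSS 4, 1 higher and 1 lower without CSS 2, and 0 without MBHIB 2, CSS 1 or CSS 3. The list median was 3.07, and 1.96 without MBHIB 4. With 1 library left out, gene lmo1186 passed without MBHIB 3 or MBHIB 4 (log2 fold change 2.30 without MBHIB 4) but not without any of the other 6 (adjusted p up to 0.0694), nor without CSS 2 and MBHIB 3 together (0.0517). Gene lmo1190 did not pass without MBHIB 1, MBHIB 2, CSS 1 or CSS 3 (up to 0.0655), and was 4.66 without MBHIB 3 and 3.01 without MBHIB 4. Gene eutB passed without MBHIB 4 (adjusted p = 8.49e-04, log2 fold change 2.0).

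The propanediol list had 12 of 19 measured members higher and 0 lower, the same counts adjusted over the list alone. With no filter on low values, 12 of 30 members were higher, and the median log2 fold change was 0.41 in place of 1.56. The adenosyltransferase gene lmo1209 (1026822 to 1027388), annotated as PduO and lying at the end of the cobalamin block, went from 30.5 ± 5.79 to 90.2 ± 7.80 (log2 fold change 1.56, standard error 0.16, adjusted p = 0.00139). The shell protein gene lmo1143 (PduT, 971818 to 972372) went from 2.11 ± 0.682 to 8.66 ± 1.44 (log2 fold change 1.83, and 0.92 with a pseudocount 10 times as large). Members that rose also included lmo1180, lmo1182 and lmo1185, annotated to ethanolamine use, and lmo1170, a threonine kinase of B12 synthesis. The propanediol dehydratase gene lmo1153 (pduC) was hardly covered in either group (0.115 ± 0.136 against 0.258 ± 0.0846, adjusted p = 0.184). Camera gave an adjusted p of 7.10e-06 at the preset correlation (adjusted p = 0.490 with an estimated correlation). The count was 7 without MBHIB 1, MBHIB 2, CSS 1, CSS 2, CSS 3 or CSS 4, each left out alone. The stretch from 970466 to 1027388 that holds these 3 groups had 56 genes tested, of which 41 were higher on salmon and 0 lower. Its bounds were set from the calls, as the outer ends of the blocks lmo1142 to lmo1149 and lmo1190 to lmo1209. Those blocks, of 8 and 20 genes, hold only higher genes by their definition.

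**Figure D2:**
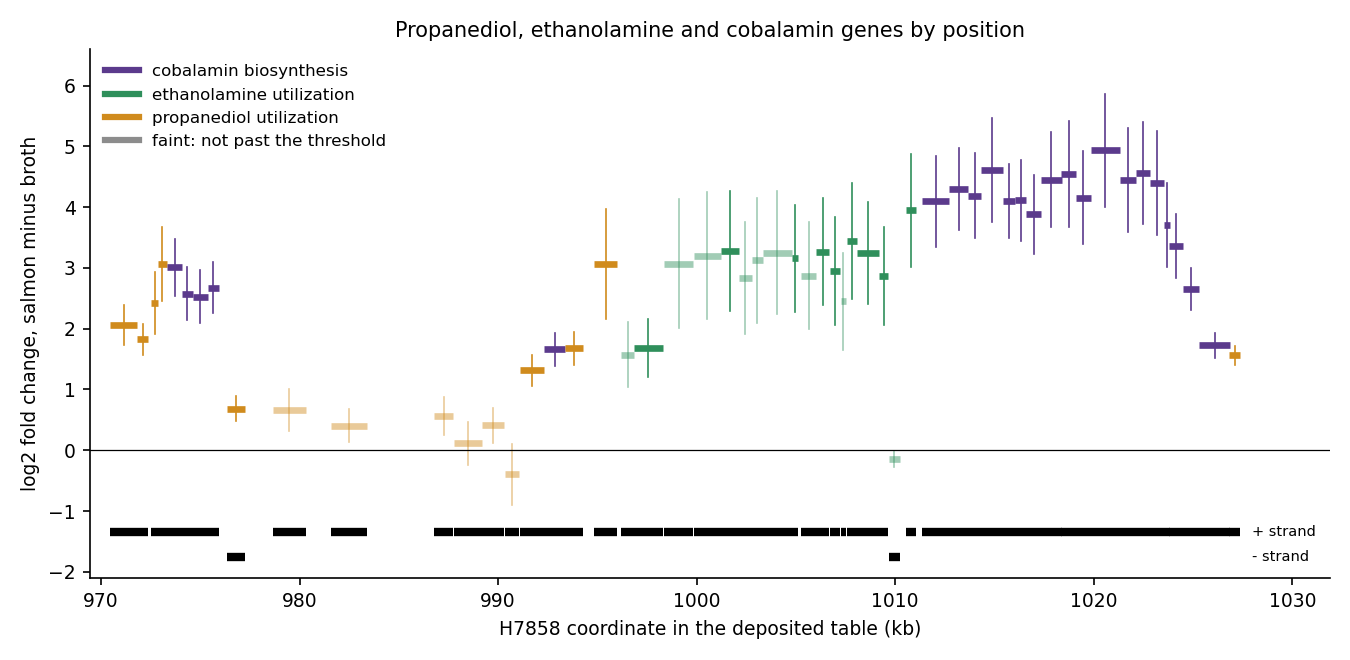
Log2 fold change (CSS minus MBHIB, bars are the standard error) of the 56 genes tested between positions 970466 and 1027388 of the authors' H7858 map, coloured by gene list, with strands drawn below and faint points for genes that did not pass the test. All 41 genes that passed lie above 0, and the bounds of the stretch were set by blocks of genes called higher.

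Of 12 measured genes that make pyrimidines, building blocks of RNA and DNA, 10 were lower on salmon and 0 higher (0 higher and 10 lower adjusted over the list alone), with a median log2 fold change of −1.89. The list passed camera at the preset correlation (adjusted p = 5.26e-06; adjusted p = 0.490 with an estimated correlation). Genes pyrE to pyrP form 1 run of 9 neighbouring lower genes (1681932 to 1692793), so they are not separate results. The carbamoyl-phosphate synthase gene carB (1684954 to 1688166, minus strand) went from 31.8 ± 8.84 to 7.40 ± 4.87 (log2 fold change −2.25, standard error 0.39, adjusted p = 0.00776), and pyrK from 18.9 ± 4.18 to 4.59 ± 2.32 (−2.03, adjusted p = 0.00564). The uracil permease gene pyrP and the aspartate carbamoyltransferase gene pyrB each had a log2 fold change of −2.13, and the uridylate kinase gene pyrH, far from the others at 1132340 to 1133068, −0.89. CSS 2 had a list median of −0.73 against the broth mean, where the other CSS libraries had −2.28 to −2.08. Gene pyrP did not pass without MBHIB 1, CSS 1, CSS 3 or CSS 4 (adjusted p up to 0.0539), nor gene pyrB without MBHIB 1, MBHIB 2, CSS 1, CSS 3 or CSS 4 (up to 0.0684).

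All 7 measured genes of the citrate cycle and pyruvate dehydrogenase list fell (0 higher and 7 lower adjusted over the list alone), among them pdhA, the E1 alpha subunit that feeds pyruvate into the cycle (894372 to 895487, 496 ± 99.1 to 250 ± 68.0, log2 fold change −1.01, adjusted p = 0.0108), and the aconitase gene citB (34.7 ± 3.06 to 18 ± 6.48, −1.0). Camera gave an adjusted p of 4.34e-04 at the preset correlation (adjusted p = 0.527 with an estimated correlation). The glycolysis list had 4 of 9 members higher and 0 lower (6 higher adjusted over the list alone), among them the aldolase gene fbaA (1041 ± 343 to 2327 ± 545, log2 fold change 1.18). Camera gave 0.00393 (adjusted p = 0.527 with an estimated correlation). In the ATP synthase list 7 of 14 members rose and 0 fell (8 higher adjusted over the list alone), including atpB (226 ± 15.2 to 400 ± 45.8, 0.81) and atpD2 (340 ± 58.2 to 651 ± 85.8, 0.94). Camera gave 0.00101 (adjusted p = 0.490 with an estimated correlation). Genes atpC to atpH form 1 run of 5 neighbouring higher genes and are not separate results. The citrate cycle count was 4 without MBHIB 1 or CSS 1, and 2 without MBHIB 2, CSS 3 or CSS 4. The glycolysis count was 2 without MBHIB 1, MBHIB 4 or CSS 1, and 1 without MBHIB 2, CSS 3 or CSS 4, and with quantile normalization the glycolysis list no longer passed (adjusted p = 0.105).

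In the list of mannose-type sugar phosphotransferase systems, 5 of 11 measured members rose and 0 fell (8 higher adjusted over the list alone), from low depths: lmo2000 went from 0.711 ± 0.0869 to 4.48 ± 2.08 (1848402 to 1849223, log2 fold change 2.06, adjusted p = 0.00564) and lmo1997 from 1.09 ± 0.991 to 7.76 ± 3.68 (2.28). Genes lmo1997 to lmo2002 form 1 run of 6 neighbouring higher genes, so members within it are not separate results. Camera gave the list an adjusted p of 4.88e-04 (adjusted p = 0.490 with an estimated correlation). The count was 1 with a 10 times stricter filter on low values, and with a pseudocount 10 times as large the log2 fold changes of gene lmo2000 and gene lmo1997 were 0.87 and 0.84, both still past the threshold. The trehalose genes lmo1254 and lmo1255 gave the largest falls among changed genes with non-overlapping groups and a known product. They were the hydrolase gene lmo1254 (1076642 to 1078288, standard error 0.67, adjusted p = 0.0159) and the trehalose transporter gene lmo1255 (17.9 ± 1.97 to 3.65 ± 5.24, log2 fold change −3.06, adjusted p = 0.0200). The lysine permease gene lmo0798 fell from 12.2 ± 5.13 to 3.0 ± 2.59 (−2.20, adjusted p = 0.0177). Gene lmo1254 did not pass without MBHIB 2 (adjusted p = 0.0543) or MBHIB 1, nor gene lmo1255 without MBHIB 1, MBHIB 2, CSS 1, CSS 3 or CSS 4 (up to 0.0657), nor gene lmo0798 without CSS 4 (0.0539). Without CSS 2, the log2 fold changes of gene lmo1254 and gene lmo1255 were −3.84 and −3.88.

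Of 10 measured members of the PrfA virulence regulon list, 6 rose and 0 fell (7 higher adjusted over the list alone). The gene actA, whose protein lets the bacterium move inside host cells (211323 to 213242), went from 0.822 ± 0.168 to 2.62 ± 0.528 (log2 fold change 1.51, standard error 0.23, adjusted p = 0.00564), the phospholipase gene plcB from 0.557 ± 0.0719 to 1.98 ± 0.318 (1.37) and hly from 1.70 ± 0.374 to 4.82 ± 1.56 (1.37, adjusted p = 0.0108). The regulator gene prfA itself did not pass (18.5 ± 4.4 against 17.1 ± 3.48, adjusted p = 0.756), nor did the internalin gene inlA (304 ± 126 against 608 ± 180, adjusted p = 0.0625). The list also holds lmo2543, a peptide chain release factor that shares the symbol prfA (62.1 ± 5.56 against 60.3 ± 5.17, adjusted p = 0.817). Camera gave an adjusted p of 5.45e-04 for the list (adjusted p = 0.490 with an estimated correlation). With a pseudocount 10 times as large, the list median fell from 1.37 to 0.72, and the log2 fold changes of gene actA, gene plcB and gene hly were 0.82, 0.45 and 0.89, each still past the threshold. A 10 times stricter filter left 7 members measured, 4 of them higher. The list median in CSS 2 was 0.78 above the broth mean, against 1.38 to 1.43 in the other CSS libraries. Without CSS 2, gene inlA passed (adjusted p = 0.0274, with a range of 0.0265 to 0.142 over all alternatives, log2 fold change 1.28).

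Flagellar and chemotaxis genes had 5 of 47 measured members higher and 0 lower (0 adjusted over the list alone). They were the chemotaxis receptor gene lmo1699 (1555268 to 1556170, 70.3 ± 18.8 to 177 ± 70.4, log2 fold change 1.27, adjusted p = 0.0204), the basal-body genes flgG (9.77 ± 2.62 to 26.3 ± 15.3, 1.27, adjusted p = 0.0372) and flgC, the flagellar biosynthesis gene lmo0681, and lmo0688, annotated as a glycosyl transferase. The flagellin gene flaA did not pass (120 ± 27.2 against 465 ± 269, adjusted p = 0.0708). Camera gave an adjusted p of 7.10e-06 at the preset correlation (adjusted p = 0.688 with an estimated correlation). CSS 2 had a list median of −0.12 against the broth mean, and the other CSS libraries 0.64 to 1.30. The count was 30 without CSS 2, 19 without CSS 2 and MBHIB 3 together, 16 with array quality weights, 0 without CSS 1, and 1 without MBHIB 1, MBHIB 2, MBHIB 3, CSS 3 or CSS 4. Gene lmo1699 did not pass without CSS 1 (adjusted p = 0.0588). With 1 library left out, gene flgG passed without MBHIB 4 or CSS 2 and not without any of the other 6 (adjusted p up to 0.0889, and up to 0.102 over all alternatives). Gene flaA passed without CSS 2 (adjusted p = 1.65e-04, log2 fold change 2.28).

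Iron and haem uptake genes had 5 of 20 members higher and 0 lower (10 higher and 1 lower adjusted over the list alone). The ferrous iron transporter gene lmo2105 (1961557 to 1963551) went from 6.72 ± 6.33 to 83.2 ± 57.1 (log2 fold change 3.73, standard error 0.63, adjusted p = 0.00876) and its neighbour lmo2104 from 8.61 ± 8.23 to 120 ± 107 (3.58, adjusted p = 0.00741). The list median against the broth mean was 4.15 in CSS 3, where CSS 1, CSS 2 and CSS 4 had 1.72, 0.70 and 0.75, and the median log2 fold change of the list was 1.81, or 0.98 without CSS 3. Both genes overlap by a few bases, and lmo2104 was at a depth of 21 in MBHIB 3 and at 281 in CSS 3. Camera gave an adjusted p of 4.88e-04 (adjusted p = 0.527 with an estimated correlation). The count was 2 without MBHIB 1, MBHIB 2 or CSS 1, 14 higher and 1 lower with array quality weights, and 7 higher and 1 lower without CSS 2 and MBHIB 3 together.

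The glutamate decarboxylase list, an acid resistance system, had 2 of 3 members higher and 0 lower (3 higher adjusted over the list alone), the decarboxylase gene gadB rising from 428 ± 261 to 2399.6 ± 829 (log2 fold change 2.92, adjusted p = 0.0369). This gene held the median of the list, which was 2.04 without MBHIB 4. Camera gave 0.0350 (adjusted p = 0.527 with an estimated correlation), and the list did not pass without CSS 1 (0.0532) or CSS 2 (0.0504). The arginine and agmatine deiminase list had 4 of 7 higher and 0 lower (5 higher and 1 lower adjusted over the list alone), led by arcB, annotated as a putrescine carbamoyltransferase (1.13 ± 0.473 to 40.3 ± 43.6, 3.85). Its CSS libraries were spread widely, with list medians of 1.96, 0.45, 3.96 and 4.90 above the broth mean in CSS 1 to 4, and the median log2 fold change of 2.95 ran from 2.30 to 3.71 with 1 library left out. Camera gave 0.0191 (adjusted p = 0.527 with an estimated correlation), and the list did not pass with a 10 times stricter filter on low values (0.678), which left 1 gene higher and a median of 0.63. Histidine synthesis had 7 of 11 lower and 0 higher (1 higher and 9 lower adjusted over the list alone), with hisB at −1.60. Camera gave 0.00398 (adjusted p = 0.527 with an estimated correlation). Genes hisA to hisZ form 1 run of 6 neighbouring lower genes and are not separate results. Nitrogen assimilation had 3 of 10 lower and 0 higher, the same adjusted over the list alone: the glutamine synthetase gene glnA (−0.83) and the glutamate synthase genes gltD (−1.76) and lmo1734 (−2.03). Camera gave 0.0191 (adjusted p = 0.527 with an estimated correlation), and the list did not pass without MBHIB 4 (0.0816). The glutamate decarboxylase count was 0 without MBHIB 1, MBHIB 2, CSS 1, CSS 3 or CSS 4, without CSS 2 and MBHIB 3 together and with quantile normalization, and MBHIB 4 had a list median of −2.62 where the other broth libraries had 0.63 to 1.00. The deiminase count was 0 without MBHIB 2, 1 without MBHIB 1, MBHIB 3 or CSS 3, and 2 without CSS 1 or CSS 4 or with a pseudocount 10 times as large. The histidine count was 1 without MBHIB 2 or CSS 4, 2 without MBHIB 3 and 3 without MBHIB 1, CSS 1 or CSS 3.

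Among heat shock chaperones and Clp proteases 6 of 20 were lower and 0 higher (the same adjusted over the list alone), including clpB (66.7 ± 7.21 to 30.8 ± 14.2, log2 fold change −1.20), clpE (−1.61) and lmo1852, annotated as a copper chaperone and no heat shock protein (−1.29). Camera gave 0.0350 (adjusted p = 0.688 with an estimated correlation). The list did not pass under 9 of 21 alternatives, among them quantile normalization (0.0742), array quality weights (0.128), a 10 times stricter filter (0.0542), members by symbol or locus tag alone (0.183), and without MBHIB 3 (0.0519), MBHIB 4 (0.238) or CSS 1 (0.0645). Uptake of compatible solutes, which protect cells from salt and cold, had 2 of 10 higher and 0 lower (the same adjusted over the list alone): the glycine betaine transporter genes gbuB (88.1 ± 40.1 to 173 ± 17, 1.08) and betL (29.1 ± 2.78 to 42.1 ± 5.93, 0.52). Camera gave 0.0350 (adjusted p = 0.527 with an estimated correlation), and that list did not pass without MBHIB 3 (0.0613), without CSS 1 (0.0919) or without CSS 2 and MBHIB 3 together (0.0693). The cold shock list did not pass (1 of 4 higher, adjusted p = 0.0817), and its member cspLB (cspB) rose from 10.3 ± 11.1 to 123 ± 119 (log2 fold change 3.25, adjusted p = 0.0290) with overlapping groups. The general stress regulon of SigB did not pass either: 4 of 57 members were higher and 6 lower (the same adjusted over the list alone), camera gave 0.783, and sigB itself had 214 ± 35.5 against 276 ± 27.6 (adjusted p = 0.0911). The heat shock count was 3 without MBHIB 1, MBHIB 2, CSS 1, CSS 3 or CSS 4. The compatible solute count was 1 without MBHIB 1, 4 without MBHIB 4 and 0 without MBHIB 2, CSS 1, CSS 3 or CSS 4. The SigB total was 4 without MBHIB 1 or MBHIB 2, 6 without CSS 1 and 5 without CSS 3 or CSS 4. Gene cspLB did not pass without MBHIB 1, MBHIB 2 or CSS 4 (adjusted p up to 0.0906), and was 2.14 with a pseudocount 10 times as large. The cold shock list passed under 4 of 21 alternatives, among them without CSS 1 (0.0344), with array quality weights (0.0469) and on the authors' normalized values (0.0490).

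**Figure D3:**
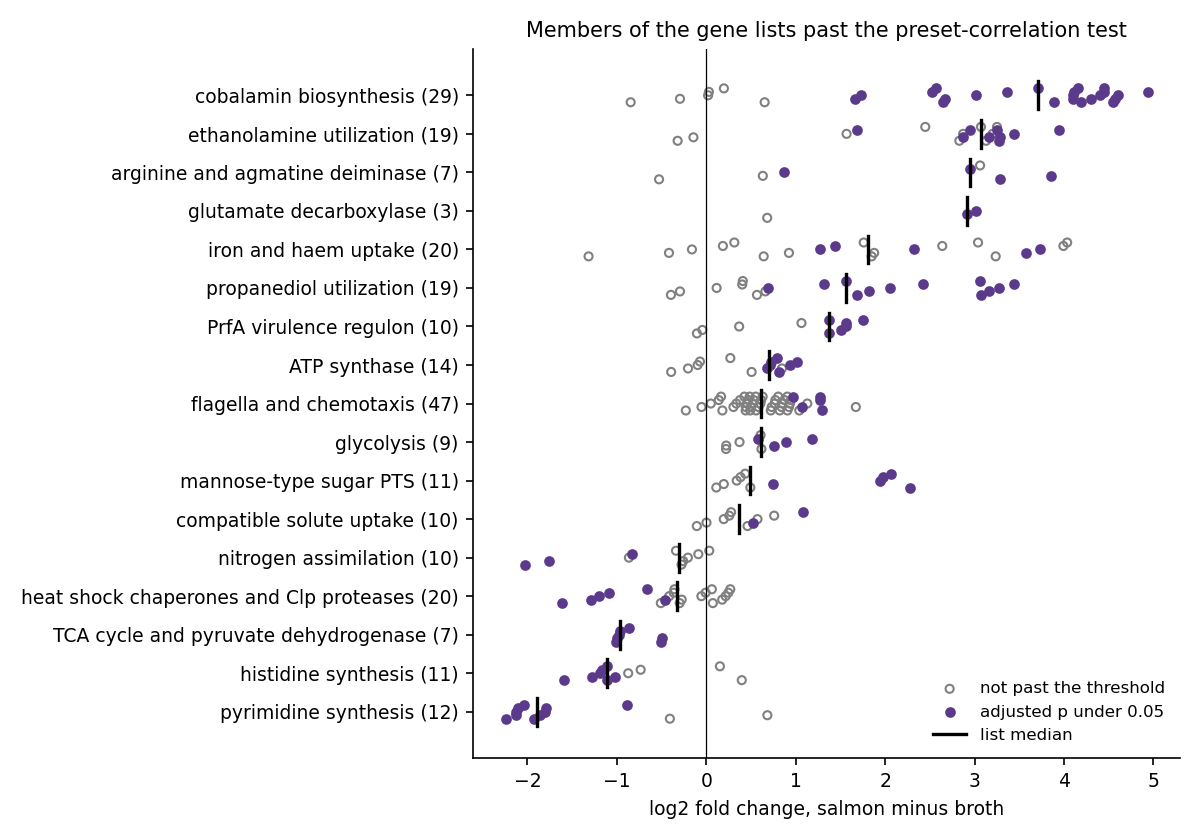
Log2 fold change (CSS minus MBHIB) of each measured member of the gene lists, 1 point per gene, filled where the adjusted p was under 0.05 and open otherwise, with a bar at the list median and the number of measured genes in brackets. The median was 3.70 for cobalamin synthesis and −1.89 for pyrimidine synthesis.

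The remaining lists did not pass camera. Cellobiose and beta-glucoside transport had 1 of 32 members higher and 4 lower (adjusted p = 0.0801; 0 higher and 4 lower adjusted over the list alone), with lmo2762 at −1.85. Glycerol use had 5 of 20 higher (0.112), among them tal2 (transaldolase, 1.82) and lmo0345 (ribose phosphate isomerase, 2.14), which act on sugars other than glycerol. Competence had 2 of 16 lower, degU (−0.54) and lmo2514 (−0.49), at 0.110. Internalins had inlB higher (1.56) and lmo0331 lower (−1.20) of 27 members (0.260). Zinc and manganese uptake had 3 of 11 higher and 1 lower (0.435; 3 higher and 2 lower adjusted over the list alone), with the zinc-binding gene lmo1671 at 1.17. Respiration had 2 of 22 higher and 4 lower (0.761), fatty acid synthesis 1 of 22 higher and 3 lower (0.260; 0 higher and 2 lower adjusted over the list alone), oligopeptide uptake 2 of 13 each way (0.753; 2 higher and 3 lower adjusted over the list alone) and cell envelope stress 0 of 16 higher and 4 lower (0.513), among them the regulator genes lisR (−0.83) and lisK (−0.86).

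Prophage and monocin genes had 4 of 59 higher and 0 lower (adjusted p = 0.177; 1 higher adjusted over the list alone). Fermentation had 3 of 12 lower, ackA1, ldh2 and alsS (0.560). Purine synthesis had guaA higher (0.36) and lmo1771 lower (−0.75) of 15 (0.579; 0 adjusted over the list alone), and oxidative stress had the thioredoxin reductase gene lmo1961 higher (2.17) and trxA lower (−0.62) of 13 (0.672). Branched-chain amino acid synthesis had alsS lower of 10 (−0.84, 0.827). No gene of the agr quorum sensing (4 measured, 0.700; agrA 125 ± 13.4 against 154 ± 34.3), branched-chain fatty acid precursor (7), potassium uptake (9) or arginine synthesis (9) lists passed in limma, the last 3 at 0.753, nor of the SOS response (9) and tryptophan synthesis (7) lists, both at 0.909. Highly conserved genes, fixed as a check for reads of other bacteria, had tuf (0.65) and rplB (0.56) higher of 11 (0.0657; 4 higher adjusted over the list alone). All 4 CSS libraries had higher list medians (0.16 to 0.28 against the broth mean) than all 4 MBHIB libraries (−0.04 to 0.09). That list passed without MBHIB 4 (0.0407), without CSS 4 (0.0388), with a pseudocount of 1 (0.0444) and with fry (0.00726), but gave 0.698 with 0 genes higher and a median of −0.06 with quantile normalization, and 0.490 with an estimated correlation. Relative to the median of all genes, which the authors' normalized values moved to −0.13, the medians of the conserved gene list (0.23 to −0.00291) and the cell envelope stress list (−0.05 to 0.05) changed sign between scalings. In the tryptophan list the median was −0.13 and the mean 0.03, and in the SOS list −0.04 and 0.04; both tests pointed up. Without CSS 1 the tryptophan median was 0.24, and without CSS 3 the SOS median was 0.12. Some of these lists passed under an alternative. Cellobiose passed without CSS 3 (0.0390) or CSS 4 (0.0198) and with a 10 times stricter filter (0.0424), prophage without CSS 1 (0.0141) or CSS 3 (0.0256), and competence with fry (0.00250). Glycerol passed without CSS 2 (0.0178), without CSS 2 and MBHIB 3 together (0.0275) and with members by symbol or locus tag alone (0.0400). With the stricter filter, which left fewer members, the medians of the glycerol (0.20 to −0.06, 11 left), prophage (0.10 to −0.08, 32 left), zinc and manganese (0.31 to −0.16, 8 left) and tryptophan lists (−0.13 to 0.41, 1 left) changed sign. Counts in these lists often moved by more than 1.5 times with a library left out: the cellobiose total ran from 0 (without MBHIB 1 or MBHIB 2) to 9 (without CSS 2), and the prophage total from 1 (without MBHIB 2 or CSS 4) to 5 (without MBHIB 3 or MBHIB 4).

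Ribosomal proteins were covered by a fixed list that matched 2 genes only, neither of which passed, and which was too small to test. A wider pattern, written after the product texts had been read, held 49 genes, of which 11 rose and 1 fell (17 higher and 1 lower adjusted over the list alone), with rpsN, annotated as an S14 protein, at 36.3 ± 15.5 against 108 ± 37.8 (log2 fold change 1.62). Camera gave an unadjusted p of 1.55e-05 for it (p = 0.275 with an estimated correlation). The total was 3 without MBHIB 1, 2 without MBHIB 2, 4 without CSS 1 or CSS 3 and 18 without MBHIB 4.

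Of 40 lists tested, 17 passed camera at its preset correlation and 0 with an estimated correlation, where the smallest unadjusted p was 0.0580, and 8 of the 35 ways of splitting the libraries into 4 and 4, the real one included, gave 17 or more. With fry, 10 of the 17 did not pass (adjusted p from 0.0516 for glycolysis to 0.230 for flagella): ethanolamine, flagella, iron, glycolysis, histidine, nitrogen, deiminase, glutamate decarboxylase, heat shock and compatible solutes. The counts of single genes within each list therefore rest on limma and not on camera. Outside the lists, the named gene with the largest rise was lmo0481, annotated as a putative antigen (341917 to 343617), from 20.2 ± 16.4 to 399 ± 141 (log2 fold change 4.48, standard error 0.49, adjusted p = 0.00511).

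**Figure D4:**
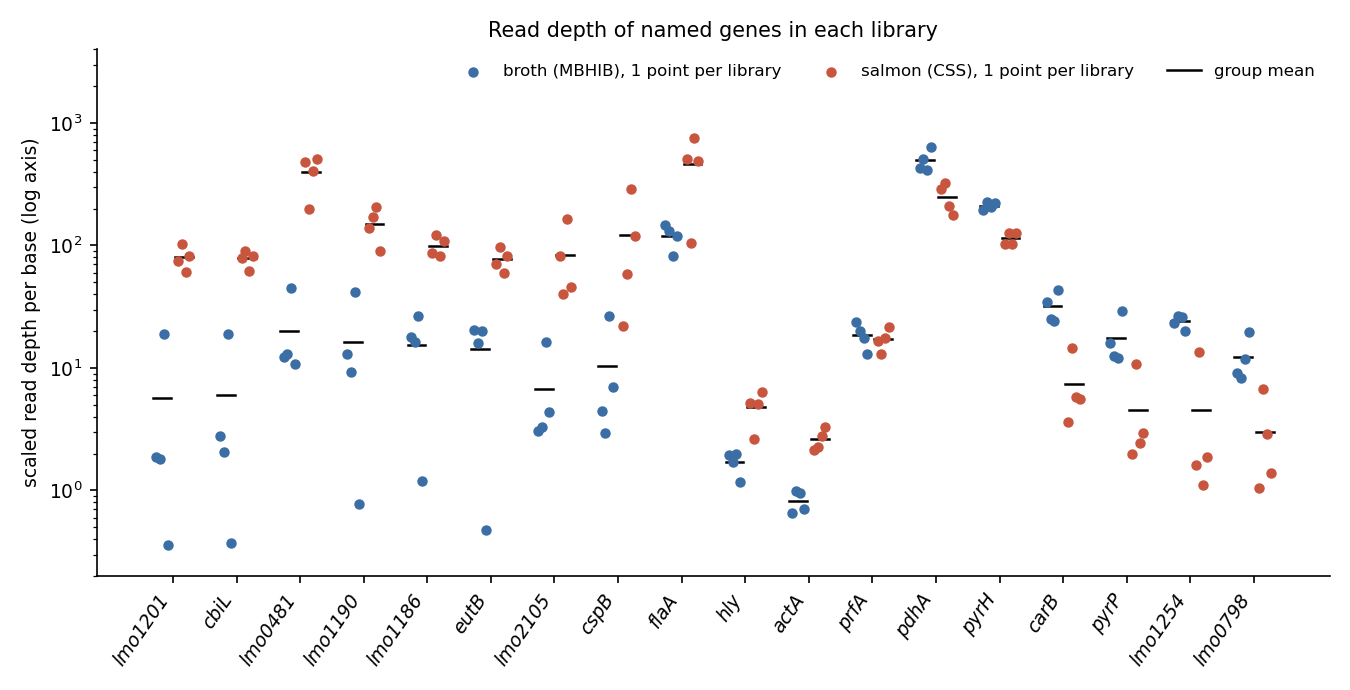
Scaled read depth per base (log axis) of named genes in each of the 8 libraries, with a bar at each group mean (n = 4 per group). For lmo0481 the CSS mean is 399 and the MBHIB mean 20.2, and for lmo1254 they are 4.5 and 24.0.

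The authors' own comparison, made with baySeq, is in the deposited tables. Taking a fold of at least 2.5 or at most 0.4 with a false discovery rate under 0.05 gave 151 genes, 88 higher and 63 lower on salmon. Of these, 148 were tested here and 141 passed, all 141 in the same direction. Of the 258 genes that changed at least 2-fold here, 118 were not among the authors' calls. The fold cutoffs differ, so these include genes such as citB, with an authors' fold of 0.473 and a false discovery rate of 0.0119. Across the 2737 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson coefficient of 0.977 and a Spearman coefficient of 0.993. For lmo0481 the authors' fold was 17.5, for lmo1201 12.6 and for lmo1254 0.177. When limma was run on the authors' normalized coverage, 208 genes were higher and 475 lower (30.5% higher, against 47.0% here), with a median log2 fold change of −0.13 over all genes, against 0.01 here.

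Ribosomal RNA made up 1.55 ± 0.246% of the summed coverage in CSS and 1.36 ± 0.282% in MBHIB (SD, n = 4), a difference of 0.191 percentage points that did not pass an exact two-sided permutation test (p = 0.286; the smallest p that 70 splits allow is 0.0286). Transfer RNA made up 0.273 ± 0.143% and 0.336 ± 0.0759% (exact permutation p = 0.429). The 10 genes with the most coverage took 12.2 ± 1.17% in CSS and 9.83 ± 0.512% in MBHIB (exact permutation p = 0.0571), and the summed coverage itself did not pass (224 ± 71.8 against 322 ± 197 in the same unit, exact permutation p = 0.4).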

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

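The tests in this part, of mixed or swapped CSS 2 and MBHIB 3 and of MBHIB 4, were chosen only after the result was seen. Values are named here where 1 library of a group of 4 stood far from the other 3 by Dixon's criterion; 12 of 124 values tested did so, where chance gives about 1 in 20.

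CSS 2 lay toward broth in several results. Its log2 scaled coverage of lmo1255 was 14.10 (other CSS libraries 10.71 to 10.93), its 10 most covered genes took 10.5% (12.8 to 12.9%), and its list medians against the broth mean were 0.78 for the PrfA regulon (1.38 to 1.43) and −0.73 for pyrimidine synthesis (−2.28 to −2.08). MBHIB 3 lay toward salmon, with 16.22 for lmo0481 (other MBHIB libraries 14.17 to 14.46) and 12.31 for lmo2104 (10.29 to 10.45).

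If reads of broth cultures had been mixed into CSS 2, all genes high on salmon would sit equally far along the way from broth to salmon; instead the median fraction was 1.28 over 48 genes of the cobalamin, ethanolamine and propanediol lists and 0.300 over 181 others, a difference of 0.984 (bootstrap 95% interval 0.879 to 1.07), which argues against mixing as the whole cause. Swapped labels of CSS 2 and MBHIB 3 are argued against too, since exchanging them left 0 changed genes in limma in place of 598, with 543 in place of 1019 at an unadjusted p under 0.05. The number of lists past camera at its preset correlation does not separate the labellings, with 18 exchanged and 17 as labelled. Reads of salmon cultures mixed into MBHIB 3 cannot be told apart from a real difference: the same difference of fractions was 0.156 (0.125 to 0.177), between the bounds set for either outcome. Both intervals resample genes within 1 library, and genes are not independent replicates. A culture on salmon in a different metabolic state, as a biological explanation, may account for CSS 2 and was not tested, since the design gives no group for it.

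MBHIB 4 lay below the other broth libraries in ethanolamine and acid resistance genes. Its log2 scaled coverage was 10.68 for lmo1186 (others 14.18 to 14.86) and 9.87 for eutB (14.44 to 14.79), and its glutamate decarboxylase list median was −2.62 (0.63 to 1.00). Against the mean of the other broth libraries, its median was −3.90 over 19 ethanolamine genes, −3.50 over 3 glutamate decarboxylase genes and −1.38 over 29 cobalamin genes.

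A wrong scale factor of MBHIB 4 would move all its genes alike and leave no gap between them. It is argued against, as the median of the 22 genes of the ethanolamine and glutamate decarboxylase lists lay at −3.83 from that of the 2715 other genes (bootstrap 95% interval −4.11 to −3.48). Those lists were picked because MBHIB 4 was low in them, and scaling itself puts the median difference of all genes near 0 (0.00378). The gap therefore restates the low values that picked the lists, and its interval is no separate support. The interval also resamples genes, which are not independent replicates. A salmon library labelled as broth is argued against as well, since the median fraction of the way from broth to salmon was −0.0182. A different physiological state of that broth culture may remain and was not tested.

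The pyrB gene had a log2 scaled coverage of 14.59 in MBHIB 4, against 13.17 to 13.41 in the other broth libraries. The lmo2000 gene had 9.59 in MBHIB 1, against 9.81 to 9.85. The PrfA list median was −0.16 in MBHIB 4, against 0.11 to 0.14.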

How the results depend on the processing

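The alternatives that left out CSS 2 and MBHIB 3 together and that took list members by symbol or locus tag alone were chosen only after the result was seen. Over the alternatives, no direction of a named gene or list that passed was reversed: named genes were on the same side of the threshold 680 times, lost it 41 times and gained it 8 times, and lists 780, 42 and 17 times. Against 598 changed genes (281 higher, 317 lower), array quality weights, which gave MBHIB 2 a weight of 5.93 and the others 0.468 to 1.13, called 1120 (564 higher, 556 lower) and 281 list members in place of 169; 594 of the 598 were shared. Leaving out single libraries gave 287 to 736 changed genes, 145 to 352 higher, 142 to 384 lower and 90 to 208 list members, with fewer samples in each fit. Lists past the threshold numbered 17 with camera, 0 with an estimated correlation and 9 with fry; the cause was not tested. The 258 genes changed at least 2-fold became 172 to 350 with a library left out. Quantile normalization called 620 genes (40.3% higher), the authors' normalized values gave 683 (30.5% higher), no filter 600, a 10 times stricter filter 566, rRNA and tRNA kept 589, a pseudocount 10 times as large 624 and of 1 576, and CSS 2 and MBHIB 3 left out together 623, of which 523 were shared with the 598. The rRNA difference ranged from 0.0830 to 0.330 percentage points.

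With the replicate block, 472 genes passed, 438 of them shared with the 598, and 18 lists. Changed members became more than 1.5 times as many in 3 lists (iron and haem 5 to 10, compatible solutes 2 to 4, and cold shock 1 to 2, which then passed camera at 0.0161). They became as much fewer in 13, such as flagella (5 to 0), ethanolamine (9 to 1), propanediol (12 to 7) and citrate cycle (7 to 3). Whether the numbers pair the samples is not known, since no label ties them. Deviations of same-numbered libraries from their group means correlated at −0.01, 0.01, 0.12 and −0.15. With 4 libraries per group, some of them far from the rest, these values cannot exclude a pairing. Alternatives meant for read counts were not run, since the tables hold coverage. Of 139 genes with a mean depth under 1 in both groups, such as lmo1153, 4 passed (2.88%), against 594 of 2598 others (22.9%). A gene that rose from such a depth, such as lmo2000 (0.711 to 4.48), counts among the others by this definition. That lowers the share of the low class, so these shares cannot show whether depth was the reason, which was not tested.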

Other observations

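In this part, the test of lower coverage of genes without an EGD-e counterpart was chosen only after the result was seen, and the runs of neighbouring genes were picked after their values were seen. A run holds by its definition only genes that changed in one direction, so the number of genes in it says nothing about a whole pathway. Maltose and maltodextrin genes lmo2121 to lmo2126 (1980391 to 1989023) formed a run of 6 higher genes with a median log2 fold change of 2.48, the maltose phosphorylase gene lmo2121 from a depth of 3.49 ± 0.405 to 13.5 ± 3.32 (SD, n = 4). Genes lmo2663 to lmo2669 (2446130 to 2453672) formed a run of 7 higher genes with a median of 1.5, annotated to galactitol except lmo2669, a membrane protein. Genes lmo2159 to lmo2163 formed a run of 5 with a median of 1.49, annotated to inositol except lmo2161, a hypothetical protein. Genes from lmo0342 to tpiA2, some of them in the glycerol list, include transketolase and transaldolase and formed a run of 5 higher genes with a median of 1.82.

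Genes from murE to mraZ, of cell wall synthesis and division except mraW, annotated as an rRNA methyltransferase, formed a run of 5 lower genes. Their median log2 fold change was −1.14. The penicillin-binding protein gene pbpB went from 146 to 69.3 and ftsL from 187 to 75.4 in mean depth. The topoisomerase IV genes parE and parC lay in a run of 5 higher genes with a median of 0.74. There were 14 runs of at least 5 neighbouring changed genes, with 97 genes in them.

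Genes changed more often beside a neighbour on the same strand that changed in the same direction: 218 such pairs were found, against a median of 48 and a range of 25 to 71 in 1000 shuffles of the gene order. This is consistent with genes of one transcript changing together, and it counts genes, not independent events.

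Genes of H7858 without an EGD-e counterpart changed less often, 21 of 241 (8.71%) against 577 of 2496 (23.1%), with an odds ratio of 0.318 (95% interval 0.191 to 0.503; two-sided Fisher exact p = 2.98e-08). They had lower coverage (median log2 mean coverage 11.5 against 14.6). Within 10 classes of mean coverage with equal numbers of genes the Mantel-Haenszel odds ratio was 0.396 (0.248 to 0.635). Lower coverage may explain part of the difference, which remained within these classes. Coverage differences inside a class and gene length were not tested. The tests treat genes as independent, which neighbouring genes are not.

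Only the real split, 1 of 35 splits of the 8 libraries into 4 and 4, gave as many as 598 changed genes. The highest other gave 0 in limma (at an unadjusted p under 0.05, 1019 against at most 543). The same held for genes changed at least 2-fold, where 1 of 35 gave as many as 258 and the highest other gave 0 in limma (at an unadjusted p under 0.05, 300 against at most 183). Every other split mixes salmon and broth libraries, which adds their difference to its spread. That lowers the counts of the other splits, and no share below 1 of 35 is possible, so these splits cannot exclude chance. Chance cannot be excluded either for the number of lists past the threshold of camera at its preset correlation. There 8 of 35 splits gave 17 or more, and the highest other gave 19.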
